A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

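The values analysed were integer read counts per gene, deposited as 1 file for each of the 12 libraries. Per the submitters' processing notes, bases were called with CASAVA 1.7, adapters were removed with cutadapt, reads were aligned with STAR to the fission yeast build ASM294v2, alignments were handled with SAMtools, and reads per gene were counted with HTSeq. Versions of these tools other than CASAVA are not given in the sources used here. Per the labels, total RNA treated with Turbo DNase was depleted of ribosomal RNA and made into stranded libraries. Each file had 7018 lines, of which 7013 were genes and 5 were HTSeq summary lines. The summary lines were kept out of the tests of genes and lists and used as shares of all reads. The line of reads outside annotated genes was also used in a test of genomic DNA. In WT, G34R, G34V and set2Δ, reads outside annotated genes took 2.02%, 2.42%, 2.38% and 3.26%, reads in overlapping genes 2.09%, 2.12%, 2.11% and 2.15%, reads not aligned 7.29%, 7.80%, 7.66% and 6.59%, reads aligned to several places 12.9%, 13.4%, 12.3% and 11.3%, and reads in genes 75.7%, 74.3%, 75.6% and 76.7%.

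Gene names, classes and neighbours came from build ASM294v3, a later build than that used for counting, and 6224 genes were matched to it: 2374 by locus tag, 3748 by symbol and 102 by an older name. Of the 789 left unmatched, 633 were antisense RNAs by name. The strand of the counts was checked on noncoding RNAs that lie wholly inside a coding gene of the other strand: 19 of 26 had more than 3 counts in every library, so counting used the strand. All values in the file of set2Δ replicate 3 were even (100% of nonzero values, 48.4 to 50.5% in the other libraries), which the notes do not explain. The file was used as deposited, and with its counts halved as an alternative chosen after the data were examined.

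Genes were kept with filterByExpr in edgeR 4.0.16 (6602 tested, 411 not), scaled by TMM (factors 0.972 to 1.04), and tested with the quasi-likelihood F-test under robust dispersions and 1 model for all 12 libraries, with 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes and called at 0.05, and a second count required a change of at least 2-fold. The common coefficient of variation between replicates was 3.32%, and the first 3 principal components took 68.3%, 11.1% and 10.4% of the variance. CPM values were computed here from the deposited counts and the scaling factors. The 6 comparisons were each mutant against WT and the mutants against each other.

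Before the data were examined, 33 gene lists were fixed: core histones, Set2 pathway and transcription chaperones, heterochromatin machinery, homologous recombination, DNA damage checkpoint, MBF targets, DNA replication, cell separation, mating and Ste11 targets, M-cell specific, P-cell specific, nitrogen starvation, early meiosis, sporulation, core environmental stress response, chaperones and heat shock, iron uptake, phosphate starvation, ergosterol synthesis, hexose transport and galactose use, glycolysis, respiratory chain, amino acid synthesis, ribosome biogenesis, strain marker genes, cytosolic ribosomal proteins, Tf2 retrotransposons, wtf genes, subtelomeric genes within 100 kb of the ends of chromosomes I and II, noncoding RNAs, antisense noncoding RNAs (at least 50% overlap with a coding gene), small nucleolar and spliceosomal RNAs, and mitochondrially encoded genes. Lists of at least 5 tested genes were tested with camera at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over 192 tests, and again with an estimated correlation and with fry. The antisense RNAs named after their sense gene are a class of the files and were not among the lists. Genes named in the text were the 10 coding genes with the largest changes in each direction against WT (5 between mutants, and 2 noncoding RNAs) with a mean of at least 5 CPM in 1 of the groups compared and no overlap of single libraries, the 4 members of each list with the lowest adjusted p, and the histone, set2 and mating-type genes used to check the labels.

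Alternatives were other scalings and filters, protein-coding genes alone, DESeq2 1.42.0, limma 3.58.1, a test against a fold of 1.5, a stricter threshold of 0.01, subtelomeres of 50 kb, and each library left out in turn. No paired analysis was possible because the labels do not link libraries across groups. Shared sequence was measured with blastn 2.17.0 (90% identity over 100 bases). In a check of the method, 50 genes per size were changed in simulated counts: of those changed 1.1-fold, 48% were found for G34R, 52% for G34V and 52% for set2Δ, and of those changed 1.25-fold 98% were found for G34R, 88% for G34V and 94% for set2Δ, with 6, 7 and 3 false calls. Only these genes were changed, while 53.4%, 50.1% and 70.1% of genes were called against WT in G34R, G34V and set2Δ. The shares found and the false calls therefore need not hold for the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Base changes and splicing were not analysed here, and reads outside annotated genes only as a total.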

Results

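RNA was profiled in 4 groups of Schizosaccharomyces pombe (fission yeast), with 3 libraries in each. Cells had wild-type histone H3 (WT), or H3 with glycine 34 replaced by arginine (H3-G34R, written G34R) or by valine (H3-G34V, written G34V). Cells of the last group had wild-type H3 and were labelled Set2D mutant, read here as a deletion of set2 (set2Δ). Set2 is the methyltransferase of H3 lysine 36, which lies near glycine 34 in the histone tail. Cultures grew overnight in rich medium at 25 °C, and each library was made from 2 µg of total RNA after depletion of ribosomal RNA. The series asks how the G34R and G34V forms of H3 differ from each other, with WT and set2Δ cells alongside. Counts assigned to genes were 160193734, 159950870 and 228726069 in the 3 WT libraries, 108430807, 198350755 and 219767664 in G34R, 169260166, 97977993 and 65797517 in G34V, and 81980085, 92608470 and 190041712 in set2Δ. At this depth 3 counts correspond to between 0.0131 and 0.0456 CPM (counts scaled to a common library size). Values of all 3 libraries of a group lay wholly above or below those of the other in 62.4% of genes for G34R against WT, 57.9% for G34V and 71.9% for set2Δ, where 10% would do so by chance. Replicates correlated at r = 0.998 to 0.999 on the log scale, and libraries of different groups at r = 0.977 to 0.996. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical, and SDs and floors cover counting error and that spread only. Values below are mean CPM ± SD with n = 3, log2 fold changes carry their standard error (SE), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

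The deleted gene was examined first. Transcripts of set2 stood at 128 ± 5.28 CPM in WT and at 3.92 ± 0.391 CPM in set2Δ, and all 3 set2Δ libraries lay between 3.69 and 4.38 CPM (log2 fold change −5.04, SE 0.052, adjusted p = 2.2e-18 in edgeR's test). In G34V set2 was at 130 ± 4.59 CPM (log2 fold change 0.02, adjusted p = 0.63 in edgeR's test), whereas in G34R it was lower, at 110 ± 1.69 CPM (−0.22, SE 0.037, adjusted p = 0.00020 in edgeR's test). Of the H3 genes, hht2 carried nearly all counts. It stood at 777 ± 18.1 CPM in WT, 696 ± 27.6 in G34R, 661 ± 21.9 in G34V and 677 ± 31.6 in set2Δ, and fell in each mutant against WT, by 0.16, 0.23 and 0.20 on the log2 scale. The other H3 genes were far lower in every group, hht1 at 0.0353 to 0.128 CPM and hht3 at 1.57 to 2.21 CPM. The H4 gene hhf2 lay between 508 and 525 CPM in the 4 groups, and the group means of hhf1 and hhf3 were at most 0.0942 and 0.0504 CPM. The labels do not say whether hht1, hht3, hhf1 and hhf3 were present in these strains, WT included, so their low values can reflect absent genes as well as low expression. The counts are given per gene, so the base changes behind the G34R and G34V labels were not examined here.

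**Figure D1:**
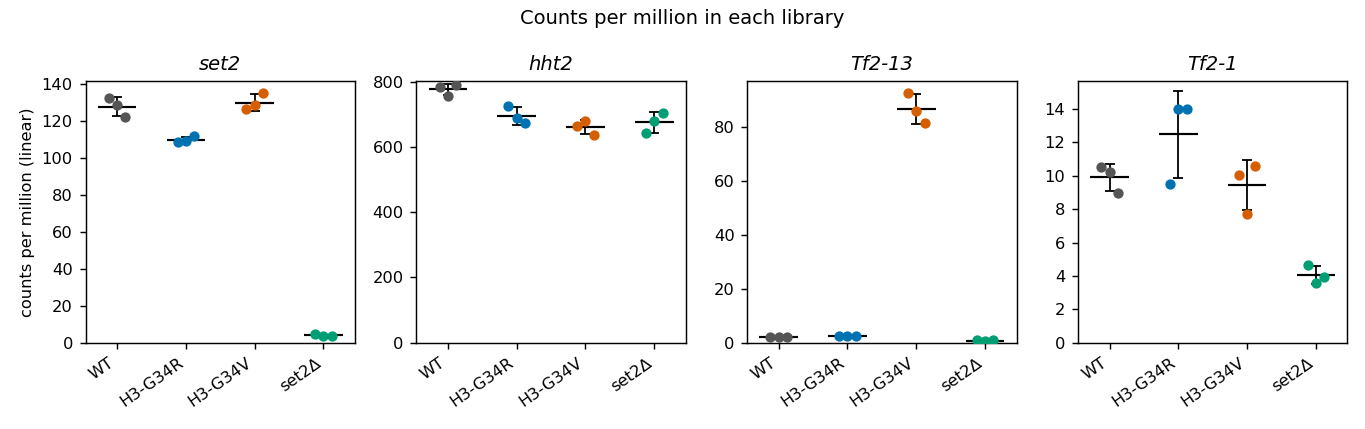
CPM (linear axis) of set2, the H3 gene hht2 and the retrotransposons Tf2-13 and Tf2-1 in each of the 12 libraries; points are libraries, horizontal lines the group means and bars ± 1 SD (n = 3). The 3 set2Δ libraries lie near 3.92 CPM for set2 against 128 CPM in WT, and Tf2-13 is at 86.8 CPM in G34V and at 2.41 CPM or less in the other groups.

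In G34R cells, mating and sporulation genes and the small heat shock protein gene hsp16 were higher than in WT, while ribosomal protein genes and genes near chromosome ends were lower. With an estimated correlation the sporulation call held, and those of mating genes (adjusted p = 0.065), ribosomal protein genes (0.89) and subtelomeric genes (0.083) did not. The transcript of hsp16 rose from 123 ± 4.53 to 445 ± 19.2 CPM (log2 fold change 1.86, SE 0.039, adjusted p = 7.7e-14 in edgeR's test). The proton pump gene pma2 rose from 6.69 ± 0.170 to 23.5 ± 1.04 CPM (1.81, SE 0.048), and grt1, which encodes a transcription factor and lies near a chromosome end, fell from 21.7 ± 0.895 to 5.74 ± 0.262 CPM (−1.93, SE 0.038). In all, 1771 of 6602 tested genes were higher and 1753 lower (1960 and 1503 with upper quartile scaling), but the changes were small: the median size among called genes was 0.18 on the log2 scale, and 42 genes rose and 16 fell by at least 2-fold.

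Of 22 tested mating genes and targets of Ste11, the transcription factor of sexual differentiation, 18 rose and none of them fell in G34R, with the same counts when adjusted over the list alone (camera adjusted p = 2.9e-11, and adjusted p = 0.065 with an estimated correlation). They included mfm3 (1.44, SE 0.060) and mfm1 (1.17, SE 0.081), which encode the M-factor pheromone, mam2 (0.83, SE 0.034), which encodes the receptor for P-factor, and spk1 (0.49, SE 0.031), which encodes the MAP kinase of the pheromone pathway. All 8 tested M-cell specific genes rose, also when adjusted over the list alone (camera adjusted p = 2.1e-09, and adjusted p = 0.0070 with an estimated correlation). This list shares members with the mating list. The rise was not limited to M-cell genes: of the 4 P-cell specific genes, map3 (0.21, SE 0.038) and map4 (0.09, SE 0.034) were called higher in G34R, and map2 and sxa1 were not called. The map4 call was lost without WT replicate 1 or 2 (adjusted p = 0.094 and 0.12) and without G34R replicate 1 or 2 (0.10 and 0.068) in edgeR's test. Of 26 sporulation genes controlled by Mei4, 17 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.0e-10, and adjusted p = 0.0036 with an estimated correlation). Examples were mde3, a protein kinase gene at 3.59 CPM in WT and 9.61 CPM in G34R, the septin genes spn6 (1.06, SE 0.028) and spn5 (1.00, SE 0.036), and mfr1 (0.98, SE 0.048), which encodes an activator of the anaphase-promoting complex in meiosis. Of 15 chaperone genes, 8 rose and 2 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0012, but adjusted p = 0.57 with an estimated correlation); beside hsp16 these were led by ssa1 (0.44, SE 0.045) and hsp104 (0.32, SE 0.035). Of 19 genes of the core environmental stress response, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0093, but adjusted p = 0.87 with an estimated correlation). The one that fell was gst2, a glutathione S-transferase gene (−0.90, SE 0.052).

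Of 136 cytosolic ribosomal protein genes 99 fell and 1 rose in G34R, or 104 and 1 adjusted over the list alone, with a median log2 fold change of −0.15 (camera adjusted p = 2.9e-07, but adjusted p = 0.89 with an estimated correlation). The lowest adjusted p among them belonged to rpl1603 (−0.25, SE 0.025). Of 33 respiratory chain genes 24 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0069, but adjusted p = 0.55 with an estimated correlation). Of 18 ergosterol synthesis genes 10 fell and 0 rose on both adjustments, that over all genes and that adjusted over the list alone (camera adjusted p = 0.014, but adjusted p = 0.54 with an estimated correlation), including erg1 (−0.28, SE 0.031) and hmg1 (−0.27, SE 0.035). Of 35 amino acid synthesis genes 17 fell and 4 rose, or 18 and 4 adjusted over the list alone (camera adjusted p = 0.024, but adjusted p = 0.93 with an estimated correlation), led by arg7 (−0.44, SE 0.033). Of 14 nitrogen starvation genes 8 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.038, but adjusted p = 0.59 with an estimated correlation), among them the amino acid permease genes put4 (−0.53, SE 0.051) and aat1 (−0.39, SE 0.032). Of 17 targets of MBF, the transcription factor of the G1/S transition, 6 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.87 with an estimated correlation), led by rep2 (−0.39, SE 0.028). The amino acid call was lost without WT replicate 1 (adjusted p = 0.065) and the MBF call without WT replicate 2 (adjusted p = 0.055). Ribosome biogenesis genes, with 18 lower and 3 higher of 49 (13 and 2 adjusted over the list alone), were not called as a list (camera adjusted p = 0.10), except without G34R replicate 3 (adjusted p = 0.028).

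Of 106 tested genes within 100 kb of the ends of chromosomes I and II, 51 fell and 14 rose in G34R, or 52 and 15 adjusted over the list alone, with a median log2 fold change of −0.22 (camera adjusted p = 3.9e-05, and adjusted p = 0.083 with an estimated correlation). Beside grt1, SPAC186.09 fell (−1.04, SE 0.064), and SPAC212.04c rose (0.98, SE 0.040). Of 713 noncoding RNAs 326 rose and 50 fell, also adjusted over the list alone (camera adjusted p = 1.1e-05, but adjusted p = 0.14 with an estimated correlation). Of the 78 among them that lie antisense to a coding gene 45 rose and 6 fell, or 46 and 7 adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.083 with an estimated correlation). SPNCRNA.871 went from 6.50 ± 0.304 to 12.8 ± 0.980 CPM (0.99, SE 0.055), and SPNCRNA.291 from 12.4 ± 0.691 to 7.67 ± 0.437 CPM (−0.69, SE 0.049). The files also count 617 tested antisense RNAs named after their sense gene, of which 444 rose and 29 fell, with a median log2 fold change of 0.27. Reads outside annotated genes made up 2.42% of reads in G34R and 2.02% in WT. Of the 12 tested Tf2 elements 5 rose and 1 fell in G34R, also adjusted over the list alone, with a median of 0.34 and no call of the list (camera adjusted p = 0.13), except without G34R replicate 1 (adjusted p = 0.0040). Genes changed by at least 2-fold numbered 58 over all classes, and 32 when only genes with at least 1 CPM in 6 libraries were tested.

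**Figure D2:**
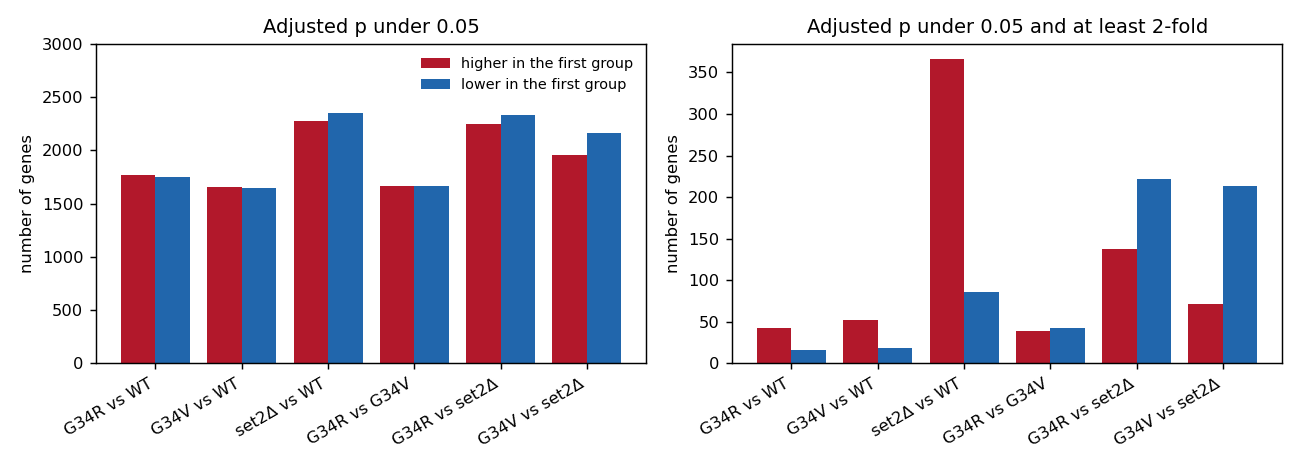
Number of genes called in each of the 6 comparisons (vertical axes, counts of genes from 0), on the left at an adjusted p under 0.05 and on the right with a change of at least 2-fold in addition; red bars are genes higher in the first group named, blue bars genes lower in it. With the TMM scaling shown, up and down calls are close in number at the first threshold (2276 and 2351 in set2Δ against WT, but 2671 and 1876 with upper quartile scaling), and at 2-fold 366 genes were higher and 86 lower in set2Δ than in WT.

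In G34V cells the largest increase was that of a single retrotransposon, Tf2-13, and genes near chromosome ends and M-cell genes were higher than in WT, while the wtf genes, MBF targets and respiratory chain genes were lower. With an estimated correlation the M-cell and wtf calls held, and those of subtelomeric genes (adjusted p = 0.097), MBF targets (0.54) and respiratory chain genes (0.41) did not. Tf2-13 rose from 1.98 ± 0.0549 to 86.8 ± 5.50 CPM (log2 fold change 5.46, SE 0.065, adjusted p = 1.7e-17 in edgeR's test), a 43.9-fold difference. SPAC212.08c and SPAC212.12, which encode GPI-anchored proteins, rose by 1.80 (SE 0.059) and 1.74 (SE 0.052), and the cell surface glycoprotein genes pfl7 and pfl9 by 1.65 (SE 0.038) and 1.44 (SE 0.057). Decreases included SPBC1289.14, an adducin gene (−2.25, SE 0.060), the urea transporter gene SPBC23G7.13c (−1.58, SE 0.059), the subtelomeric helicase gene tlh2 (−1.53, SE 0.089), the hexose transporter gene ght6 (−1.26, SE 0.071) and the metallothionein gene zym1 (−1.07, SE 0.035). The related gene tlh1 was at 0.22 in G34V. Reads that aligned to several places were left out of the counts, so single values of tlh1 and tlh2 are uncertain. In all, 1657 genes were higher and 1649 lower, and with upper quartile scaling 2032 were higher and 1165 lower. The median size among called genes was 0.18 on the log2 scale, and 52 genes rose and 18 fell by at least 2-fold.

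Subtelomeric genes moved upwards in G34V: 53 of 106 rose and 16 fell, or 53 and 17 adjusted over the list alone, with a median log2 fold change of 0.26 (camera adjusted p = 4.2e-07, and adjusted p = 0.097 with an estimated correlation). The 44 of them with a similar stretch in another gene, whose reads could be shared, had a median of 0.56. The 62 without such a stretch had a median of 0.07. The arylsulfatase gene SPBPB10D8.02c rose from 19.9 to 53.1 CPM. The wtf genes, a family that includes meiotic drivers, fell: 21 of 25 were lower and 4 higher, also adjusted over the list alone, with a median of −0.32 (camera adjusted p = 5.8e-06, and adjusted p = 0.013 with an estimated correlation). Examples were wtf25 (−0.74, SE 0.053) and wtf9 (−0.57, SE 0.041), and members of this family share sequence, so single values are uncertain. Of the 12 tested Tf2 elements, Tf2-13 rose, Tf2-11 fell from 717 ± 23.1 to 399 ± 18.6 CPM (−0.84, SE 0.037), Tf2-2 was called lower (−0.18, SE 0.057) and 9 were not called. Adjusted over the list alone the counts were also 1 higher and 2 lower. As a list they were not called (camera adjusted p = 0.051, and adjusted p = 0.84 with an estimated correlation), and their mean (0.33) and median (−0.04) differed in sign. The list was called without G34V replicate 1, 2 or 3 (adjusted p = 0.0079, 0.022 and 0.022) and without a filter on low counts (0.048). Tf2 copies are nearly identical, and reads that aligned to several places were left out of the counts. The call of Tf2-2 was lost without WT replicate 2 or 3 (adjusted p = 0.052 and 0.083) and without G34V replicate 2 or 3 (0.071 and 0.094).

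Of the 8 M-cell specific genes 6 rose in G34V, also adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.022 with an estimated correlation), with mfm3 at 1.30 (SE 0.062) and mam2 at 0.69 (SE 0.035). The P-cell genes map4 (0.17, SE 0.034), map2 (0.12, SE 0.037) and map3 (0.11, SE 0.040) were called higher in G34V as well, and sxa1 was not called. In edgeR's test the map2 call was lost without WT replicate 2 (adjusted p = 0.057), and the map3 call without WT replicate 2 (0.087) and without G34V replicate 1 or 2 (0.11 and 0.094). Of 22 mating genes 15 rose and 1 fell (camera adjusted p = 0.00012, but adjusted p = 0.39 with an estimated correlation). Of 26 sporulation genes 15 rose and 6 fell (camera adjusted p = 0.00044, and adjusted p = 0.11 with an estimated correlation). Both lists had the same counts adjusted over the list alone. Of 15 chaperone genes 9 rose, and 1 fell only when adjusted over the list alone (camera adjusted p = 0.034, but adjusted p = 0.83 with an estimated correlation), led by hsp104 (0.37, SE 0.035). Of 49 ribosome biogenesis genes 28 rose, or 29 adjusted over the list alone (camera adjusted p = 0.019, but adjusted p = 0.92 with an estimated correlation), led by nop2 (0.21, SE 0.030). Noncoding RNAs rose in 268 cases and fell in 67 of 713, or 262 and 67 adjusted over the list alone (camera adjusted p = 0.0027, but adjusted p = 0.19 with an estimated correlation). Those antisense to coding genes rose in 39 and fell in 3 of 78 cases, or 40 and 3 adjusted over the list alone (camera adjusted p = 0.00090, and adjusted p = 0.097 with an estimated correlation). SPNCRNA.293 rose by 1.58 (SE 0.060) and SPNCRNA.397 changed by −1.27 (SE 0.071). Of the 617 antisense RNAs named after their sense gene 379 rose and 41 fell, with a median of 0.23. Reads outside annotated genes made up 2.38% of reads in G34V and 2.02% in WT.

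Of 17 MBF targets 15 fell and 0 rose in G34V, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.3e-05, but adjusted p = 0.54 with an estimated correlation). They included rep2 (−0.44, SE 0.028), cig2, the S-phase cyclin gene (−0.44, SE 0.032), and ctp1, which acts in DNA end resection (−0.34, SE 0.029). Of 33 respiratory chain genes 23 fell, or 24 adjusted over the list alone (camera adjusted p = 0.00090, but adjusted p = 0.41 with an estimated correlation). Of 17 genes of hexose transport and galactose use 5 fell and 2 rose (camera adjusted p = 0.039, but adjusted p = 0.91 with an estimated correlation), with fbp1, a gluconeogenesis gene, at −0.74 (SE 0.085). Of 19 core stress response genes 6 fell and 3 rose (camera adjusted p = 0.038, but adjusted p = 0.91 with an estimated correlation). Both had the same counts adjusted over the list alone. Several of these calls rested on single libraries. Without G34V replicate 3 the stress (adjusted p = 0.18), hexose (0.11) and ribosome biogenesis (0.11) lists were not called, without G34V replicate 2 the chaperones were not (0.064), without WT replicate 1 hexose was not (0.064), and without WT replicate 2 stress (0.055) and chaperones (0.061) were not.

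In set2Δ cells nearly all genes near chromosome ends were higher than in WT, by more than in either H3 mutant, and all 12 tested Tf2 elements were lower. With an estimated correlation the subtelomeric call held and that of the Tf2 elements did not (adjusted p = 0.19). Of 106 subtelomeric genes 99 rose and 3 fell, with the same counts adjusted over the list alone and a median log2 fold change of 1.96 (camera adjusted p = 1.1e-95, and adjusted p = 0.00077 with an estimated correlation). SPAC869.04, annotated as formamidase-like, went from 0.556 ± 0.0715 to 58.4 ± 1.09 CPM (6.69, SE 0.065, adjusted p = 5.7e-19 in edgeR's test), and SPAC186.03, an asparaginase gene, from 0.923 ± 0.121 to 72.9 ± 1.62 CPM (6.28, SE 0.075). The urea transporter gene SPAC869.03c rose by 5.53 (SE 0.096), the amidase gene SPAC869.01 by 5.40 (SE 0.081), the glycoprotein gene pfl9 by 4.85 (SE 0.050), and grt1, which was lower in G34R, by 2.67 (SE 0.033). The median was at least 1.67 at each of the 4 chromosome ends. Across all genes 2276 were higher and 2351 lower (2671 and 1876 with upper quartile scaling), with a median size of 0.24 on the log2 scale among called genes, and 366 rose and 86 fell by at least 2-fold. Restricted to protein-coding genes, 162 genes changed by at least 2-fold against 452 over all classes.

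**Figure D3:**
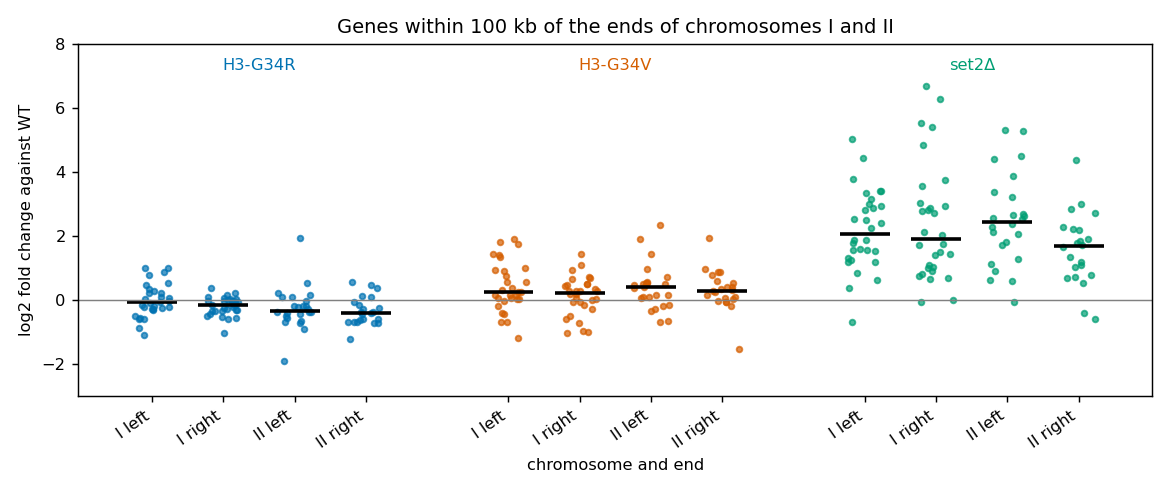
Log2 fold change against WT (vertical axis) of each tested gene within 100 kb of the 4 ends of chromosomes I and II, for G34R, G34V and set2Δ; points are genes, spread sideways at random, and black lines are medians. The medians lie between 1.67 and 2.44 in set2Δ, between 0.21 and 0.39 in G34V, and between −0.41 and −0.09 in G34R.

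Transcripts of the Tf2 retrotransposons fell in set2Δ for all 12 tested elements, also adjusted over the list alone, with a median log2 fold change of −1.28 (camera adjusted p = 2.2e-08, but adjusted p = 0.19 with an estimated correlation). Tf2-11 went from 717 ± 23.1 to 155 ± 3.40 CPM (−2.21, SE 0.039) and Tf2-2 from 111 ± 4.18 to 37.7 ± 1.33 CPM (−1.56, SE 0.059); single elements are uncertain because their sequences are nearly identical. Of 35 amino acid synthesis genes 30 fell and 3 rose (camera adjusted p = 7.8e-06, but adjusted p = 0.65 with an estimated correlation), led by arg4 (−0.81, SE 0.043). All 14 strain marker genes, which overlap this list, fell (camera adjusted p = 0.0042, but adjusted p = 0.55 with an estimated correlation). Among these markers ura4 was low in every group, with means of 0.150 to 0.288 CPM, and its set2Δ and WT libraries overlapped. Of 18 genes of the Set2 pathway and of transcription chaperones 11 fell and 3 rose (camera adjusted p = 0.0015, and adjusted p = 0.065 with an estimated correlation). This list contains set2 itself, and without it, a test chosen after the values were seen, 10 of 17 fell and 3 rose with no call (camera adjusted p = 0.23). Its other leading members were hip1 (−0.46, SE 0.029) and hip3 (−0.41, SE 0.020), subunits of the HIRA histone chaperone. Of 33 respiratory chain genes 28 fell (camera adjusted p = 0.012, but adjusted p = 0.57 with an estimated correlation). Of 18 ergosterol genes 13 fell and 1 rose (camera adjusted p = 0.017, but adjusted p = 0.55 with an estimated correlation). The counts of these 5 lists did not differ when adjusted over the list alone. Cytosolic ribosomal protein genes were not called as a list in set2Δ, except without set2Δ replicate 3 (camera adjusted p = 0.013). Among single genes spo13 went from 5.17 ± 0.309 to 0.681 ± 0.149 CPM (−2.95, SE 0.106), the ammonium transporter gene amt3 changed by −1.33 (SE 0.050) and SPBC1289.14 by −1.33 (SE 0.056).

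Sporulation genes moved in both directions in set2Δ, 17 higher and 7 lower of 26, also adjusted over the list alone (camera adjusted p = 0.021 upwards, and adjusted p = 0.22 with an estimated correlation). The meiotic genes meu6 (1.55, SE 0.040) and mfr1 (1.32, SE 0.049) rose, while agn2, the glucanase gene for the opening of the ascus, fell from 48.0 ± 1.49 to 13.8 ± 0.742 CPM (−1.80, SE 0.037). Of 15 chaperone genes 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.035, but adjusted p = 0.83 with an estimated correlation), led by hsp104 (0.85, SE 0.035). Noncoding RNAs rose in 342 cases and fell in 140 of 713, or 340 and 139 adjusted over the list alone (camera adjusted p = 0.038, but adjusted p = 0.42 with an estimated correlation). Those antisense to coding genes rose in 49 cases and fell in 10 of 78, or 49 and 11 adjusted over the list alone (camera adjusted p = 0.00084, and adjusted p = 0.083 with an estimated correlation). The noncoding RNA prl61 rose from 1.39 ± 0.0829 to 33.6 ± 2.10 CPM (4.58, SE 0.067) and SPNCRNA.287 by 3.42 (SE 0.075). Among the 617 antisense RNAs named after their sense gene 479 rose and 54 fell, with a median of 0.54, and 132 rose by at least 2-fold, against 9 in G34R and 4 in G34V. These RNAs took 1.07% ± 0.0161 of gene counts in set2Δ and 0.678% ± 0.0093 in WT, and reads outside annotated genes took 3.26% and 2.02% of reads. The chaperone call was lost without WT replicate 2 (adjusted p = 0.055), and that of the noncoding RNAs without WT replicate 1 (0.056), without set2Δ replicate 2 (0.058) and without a filter on low counts (0.084).

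**Figure D4:**
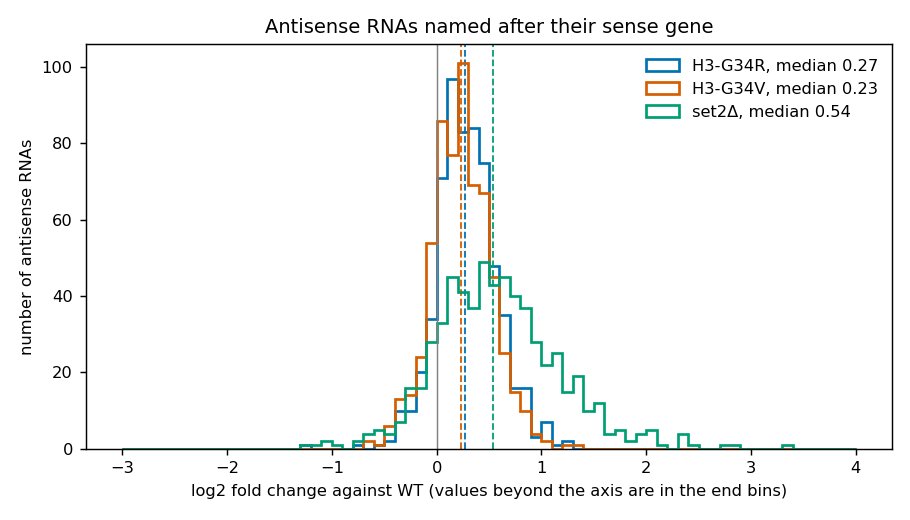
Distribution of log2 fold changes against WT (horizontal axis) of 617 antisense RNAs named after their sense gene, as the number of RNAs per bin (vertical axis), for G34R, G34V and set2Δ; dashed lines are medians. The medians are 0.27 in G34R, 0.23 in G34V and 0.54 in set2Δ.

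The H3 mutants were then set against each other. Compared with G34V, G34R had lower transcripts of genes near chromosome ends, of ribosome biogenesis and of amino acid synthesis, and higher transcripts of the wtf genes, of hsp16 and of 8 of 19 stress genes. With an estimated correlation the subtelomeric and wtf calls held, and those of ribosome biogenesis (adjusted p = 0.65), amino acid synthesis (0.77) and stress genes (0.43) did not. In G34R hsp16 was 3.67-fold higher than in G34V (log2 fold change 1.88, SE 0.039, adjusted p = 5.1e-14 in edgeR's test), and pma2 (1.62, SE 0.050), ght6 (1.61, SE 0.071), and the glucosidase gene SPBC2G2.17c (1.56, SE 0.047) followed. Tf2-13 was lower in G34R than in G34V (−5.16, SE 0.064), as were SPBPB10D8.02c (−1.82, SE 0.047), pfl9 (−1.77, SE 0.060) and grt1 (−1.62, SE 0.040). In all 1667 genes were higher and 1670 lower in G34R, 39 and 42 of them by at least 2-fold, and with upper quartile scaling 1457 were higher and 1888 lower. With only genes of at least 1 CPM in 6 libraries tested, 47 genes in place of 81 changed by at least 2-fold.

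Of the subtelomeric genes 73 of 106 were lower in G34R than in G34V and 11 higher, or 75 and 12 adjusted over the list alone, with a median of −0.49 (camera adjusted p = 3.3e-23, and adjusted p = 0.013 with an estimated correlation). The median was −0.78 for the 44 genes with a similar stretch in another gene and −0.36 for the 62 without. Of 25 wtf genes 22 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.0070 with an estimated correlation), led by wtf14 (0.28, SE 0.019) and wtf13 (0.58, SE 0.042). Of 19 core stress response genes 8 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 1.1e-07, but adjusted p = 0.43 with an estimated correlation). Beside hsp16 these were zym1 (1.19, SE 0.036) and the calcium-transporting ATPase gene cta3 (1.14, SE 0.041). Of 22 mating genes 12 were higher and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.022, but adjusted p = 0.57 with an estimated correlation). This call was lost without G34V replicate 3 (adjusted p = 0.056). Of 26 sporulation genes 16 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.031, but adjusted p = 0.27 with an estimated correlation). Ribosome biogenesis genes were lower in 43 of 49 cases, or 45 adjusted over the list alone (camera adjusted p = 5.8e-06, but adjusted p = 0.65 with an estimated correlation). Ribosomal protein genes were lower in 77 of 136, or 82 (camera adjusted p = 1.2e-05, but adjusted p = 0.91 with an estimated correlation). Amino acid synthesis genes were lower in 24 of 35, or 24 (camera adjusted p = 0.00012, but adjusted p = 0.77 with an estimated correlation). None of these 3 lists had a member that was called higher. The antisense RNAs named after their sense gene were higher in 208 and lower in 151 of 617 cases, with a median of 0.04.

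Both H3 mutants were also set against set2Δ. Subtelomeric genes were lower in both, with 100 of 106 lower in G34R and 96 of 106 in G34V, and 4 and 7 higher, all with the same counts adjusted over the list alone. The medians were −2.22 and −1.81 (camera adjusted p = 5.4e-121 and 1.4e-100, and adjusted p = 0.00077 and 0.00071 with an estimated correlation). SPAC869.04 was lower than in set2Δ by a log2 fold change of −6.74 (SE 0.066) in G34R and −6.03 (SE 0.066) in G34V. All 12 Tf2 elements were higher than in set2Δ in both H3 mutants, also adjusted over the list alone (camera adjusted p = 2.9e-11 and 6.2e-17, and adjusted p = 0.15 and 0.065 with an estimated correlation). Tf2-11 differed by 2.06 (SE 0.039) in G34R and Tf2-13 by 6.88 (SE 0.079) in G34V. Amino acid synthesis genes were higher in 28 and lower in 5 of 35 cases in G34R (camera adjusted p = 0.0012, but adjusted p = 0.86 with an estimated correlation). In G34V they were higher in 30 and lower in 3 (camera adjusted p = 4.2e-11, but adjusted p = 0.43 with an estimated correlation). The pheromone gene mfm1 was higher by 2.18 (SE 0.087) and 1.44 (SE 0.088), and agn2 by 2.02 (SE 0.037) and 1.78 (SE 0.038). Part of the mfm1 difference lay in set2Δ, where it stood at 25.4 ± 2.08 CPM against 51.4 ± 3.69 in WT. Of other M-cell genes, mam2 (32.1 and 23.3 CPM) and mfm2 (217 and 174 CPM) had higher means in set2Δ than in WT. The mean of mat1-Mi was lower (0.465 and 0.560 CPM). The noncoding RNA prl61 was lower (−4.46, SE 0.066, and −4.24, SE 0.070). In all, 2244 genes were higher and 2336 lower in G34R than in set2Δ, 138 and 222 of them by at least 2-fold, and 1955 were higher and 2168 lower in G34V, 71 and 213 by at least 2-fold. Upper quartile scaling gave 1955 higher and 2628 lower in G34R, and 1783 and 2311 in G34V. With a filter of 1 CPM in 6 libraries, 238 in place of 360 genes differed by at least 2-fold in G34R, and with protein-coding genes only 163 in G34R and 130 in place of 284 in G34V.

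Smaller lists differed between the H3 mutants and set2Δ as well. The Set2 pathway list, which includes set2, was called in G34R (10 up and 4 down of 18, camera adjusted p = 0.0029, and adjusted p = 0.080 with an estimated correlation). It was called in G34V too (8 up and 2 down, camera adjusted p = 0.00012). There the call held with an estimated correlation (camera adjusted p = 0.032), unlike in G34R. Without set2 neither comparison was called (camera adjusted p = 0.29 and 0.18), so these calls rest on the deleted gene. M-cell genes were higher in G34R (5 up and 0 down of 8, camera adjusted p = 0.019, but adjusted p = 0.16 with an estimated correlation). The same was seen in G34V (6 up and 1 down, camera adjusted p = 0.038, but adjusted p = 0.22 with an estimated correlation). Phosphate starvation genes were higher in G34R (5 up and 1 down of 6, camera adjusted p = 0.021, but adjusted p = 0.22 with an estimated correlation). The same was seen in G34V (4 up and 2 down, camera adjusted p = 0.012, but adjusted p = 0.17 with an estimated correlation). Strain marker genes were higher in G34R (12 up and 0 down of 14, camera adjusted p = 0.047, but adjusted p = 0.75 with an estimated correlation). The same was seen in G34V (12 up and 0 down, camera adjusted p = 0.00029, but adjusted p = 0.40 with an estimated correlation). The G34R call of the marker genes was lost without G34R replicate 1 (adjusted p = 0.058) and without set2Δ replicate 1 or 2 (0.064 and 0.064). The list of hexose transport and galactose use shares ght3, ght7, gal1, gal7, gal10 and mel1 with the subtelomeric list, and was not tested without them. It was called downwards in G34R although its members were split (9 down and 7 up of 17, camera adjusted p = 0.027, but adjusted p = 0.91 with an estimated correlation). In G34V the list was called downwards as well (10 down and 3 up, camera adjusted p = 0.00090, but adjusted p = 0.71 with an estimated correlation). Mating genes were called in G34R against set2Δ (14 up and 4 down of 22, camera adjusted p = 0.017, but adjusted p = 0.57 with an estimated correlation). All these counts were the same adjusted over the list alone.

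**Figure D5:**
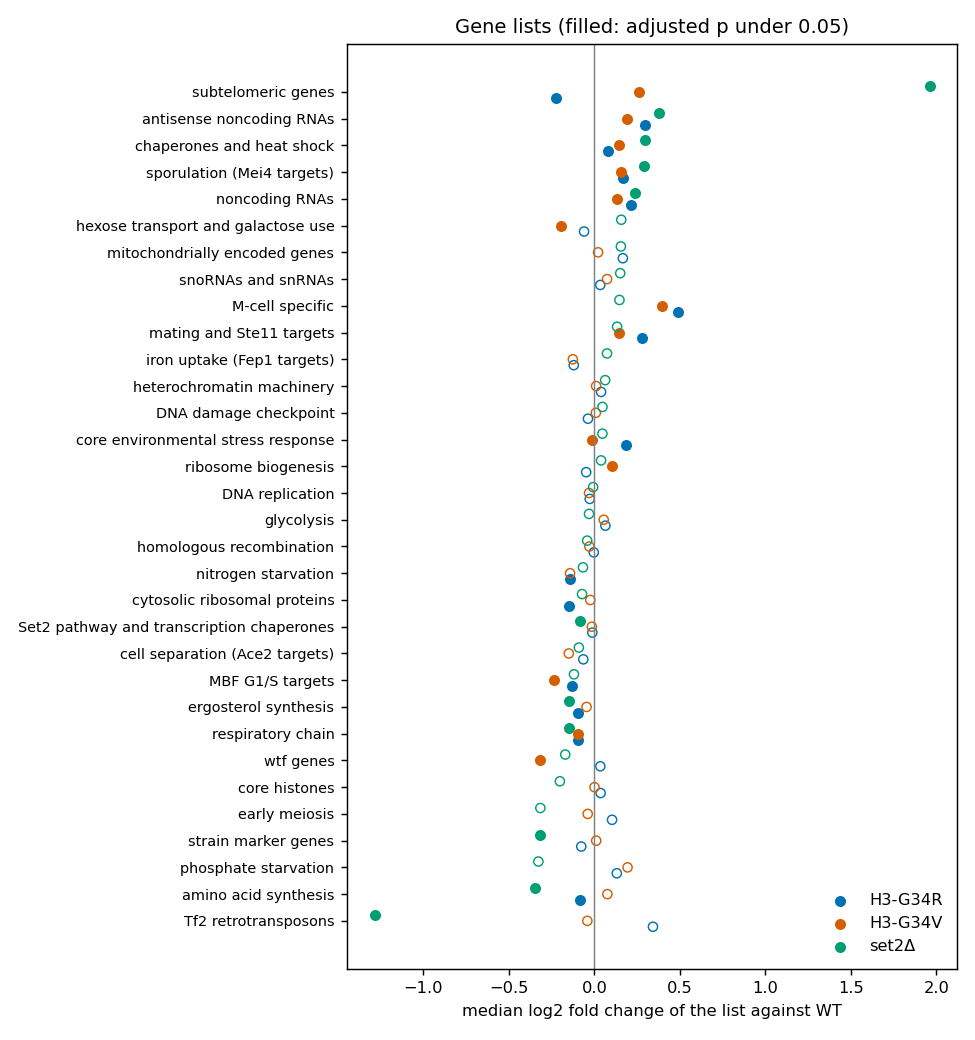
Median log2 fold change against WT (horizontal axis) of the tested members of each of 32 gene lists, for G34R, G34V and set2Δ; filled circles have a camera adjusted p under 0.05 with the preset correlation of 0.01. The subtelomeric genes stand at 1.96 in set2Δ, 0.26 in G34V and −0.22 in G34R, and the Tf2 elements at −1.28 in set2Δ.

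With camera, 5 lists tied to chromatin and to DNA damage were not called in any of the 6 comparisons, while fry, which compares a list with no change and not with other genes, called some of them. Against WT fry called DNA replication downwards (adjusted p = 3.2e-06 in G34R, 5.1e-05 in G34V and 0.00011 in set2Δ) and heterochromatin genes upwards (0.0089, 0.025 and 0.00041). It also called homologous recombination downwards in G34V (0.0059) and set2Δ (0.0060), and histones downwards in set2Δ (0.013). Of 24 heterochromatin genes 9 rose and 6 fell in G34R, 9 and 5 in G34V and 13 and 5 in set2Δ, with camera adjusted p = 0.75, 0.85 and 0.89. The HP1 gene swi6 changed by 0.19 (SE 0.024) in G34R and the RNA-dependent RNA polymerase gene rdp1 by 0.41 (SE 0.024) in set2Δ. Of 31 homologous recombination genes 6 rose and 7 fell in G34R (6 and 6 adjusted over the list alone), 4 and 9 in G34V, and 8 and 13 in set2Δ (camera adjusted p = 0.75, 0.46 and 0.53). The gene rti1 changed by −1.20 (SE 0.074) in set2Δ and mre11 by 0.24 (SE 0.022) in G34R. Of 16 checkpoint genes 3 rose and 3 fell in G34R, 3 and 4 in G34V (2 and 3 adjusted over the list alone) and 6 and 4 in set2Δ (camera adjusted p = 0.71, 0.89 and 0.93). Of 34 DNA replication genes 2 rose and 14 fell in G34R, 4 and 10 in G34V and 9 and 11 in set2Δ (camera adjusted p = 0.16, 0.37 and 0.53). Of 10 genes of the core histone list, which includes the histone variant genes pht1 and cnp1, the counts were 2 and 2, 1 and 2, and 2 and 4 (0.97, 0.89 and 0.71). In set2Δ the means of pht1 (57.0 CPM) and cnp1 (28.4 CPM) were above those in WT (45.8 and 23.2 CPM). Those of hht2, hta1, hta2 and htb1 were below WT. For these 5 lists, counts adjusted over the list alone were the same where no second count is given.

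Of 25 early meiosis genes 11 rose and 3 fell in G34R, 4 and 8 in G34V and 4 and 17 in set2Δ (camera adjusted p = 0.37, 0.55 and 0.22). Of 12 targets of the iron regulator Fep1 the counts were 2 and 5, 2 and 7, and 4 and 1 (0.22, 0.15 and 0.91). Of 13 glycolysis genes they were 3 and 1, 2 and 1, and 1 and 5 (0.40, 0.82 and 0.68), or 3 and 0, 1 and 1, and 1 and 5 adjusted over the list alone. Of 6 phosphate starvation genes they were 4 and 1, 4 and 1, and 1 and 5 (0.13, 0.32 and 0.17). Of 9 cell separation genes 0 rose, and 0, 2 and 1 fell (0.68, 0.23 and 0.73), or 0, 2 and 0 adjusted over the list alone. Of 39 small nucleolar and spliceosomal RNAs 5 rose and 3 fell in G34R, 9 and 5 in G34V and 17 and 6 in set2Δ (0.99, 0.89 and 0.85), or 5 and 2, 8 and 5, and 17 and 4 adjusted over the list alone. Of 18 mitochondrially encoded genes the counts were 7 and 0, 5 and 3, and 8 and 2 (0.47, 0.92 and 0.87), or 7 and 0, 5 and 2, and 7 and 2 adjusted over the list alone. The counts of early meiosis, iron and phosphate genes did not differ between the adjustments. In G34R the median of the small RNAs was 0.03 while camera pointed downwards, and in set2Δ that of the checkpoint genes was 0.05 while camera pointed downwards. Early meiosis genes were called between G34R and G34V without G34R replicate 3 (adjusted p = 0.045), and between G34R and set2Δ without G34R replicate 3 (0.040) or set2Δ replicate 1 (0.043), and iron genes in G34V without WT replicate 3 (0.049). With an estimated correlation the calls that held were M-cell and sporulation genes in G34R, M-cell and wtf genes in G34V, subtelomeric genes in set2Δ and in all 3 comparisons between mutants, and wtf genes between G34R and G34V. The Set2 pathway call between G34V and set2Δ also held, but only with set2 in the list. The P-cell specific list had 4 tested genes, too few for a test of the list, and in set2Δ map4 (0.56, SE 0.034) and map2 (0.40, SE 0.036) rose while map3 (−0.09) and sxa1 (−0.04) were not called.

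The calls of the 3 mutants against WT overlapped. Genes called in the same direction in G34R and set2Δ numbered 1010 higher and 897 lower, where independent lists would share 610.5 and 624.2, and 729 genes were called in opposite directions. For G34V and set2Δ the numbers were 1178 and 1069 against 571.2 and 587.2, with 364 opposite, and for G34R and G34V 974 and 797 against 444.5 and 437.9, with 297 opposite. In all 3 mutants 739 genes were higher and 536 lower. All comparisons share the 3 WT libraries. In 100 simulated sets of unchanged groups against those libraries, at most 1 gene was called in the same direction in both groups. Those sets hold no changed genes, so few calls of any kind are fixed in advance and give no level for the observed overlap. The covariance of log2 fold changes was 0.0304 for G34R and set2Δ, 0.0837 for G34V and set2Δ and 0.0369 for G34R and G34V, against simulated means of 0.00271, 0.00271 and 0.00272, which leaves differences of 0.0277, 0.0810 and 0.0342. The correlations across genes were 0.19, 0.49 and 0.48, with simulated means of 0.46, 0.42 and 0.44. Genes are not independent replicates, and 3 WT libraries cannot be divided into parts of at least 2 each, so part of the excess can come from the shared controls. Counted only over genes changed by at least 2-fold, the shared calls were 15, 43 and 12.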

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

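Reads outside annotated genes took 2.42% of reads in G34R, 2.38% in G34V and 3.26% in set2Δ, against 2.02% in WT, and reads in overlapping genes 2.12% in G34R and 2.15% in set2Δ, against 2.09% in WT. All nonzero values of set2Δ replicate 3 were even (100%). Between the H3 mutants, core stress response genes had a median log2 fold change of 0.15 and subtelomeric genes one of −0.49 in G34R against G34V.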

How the results depend on the processing

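Most results kept their sign and call under the other settings, and the cause of each change below was not tested unless the setting itself sets it. Against a fold of 1.5 the genes changed numbered 82 for G34R against WT, 99 for G34V against WT, 641 for set2Δ against WT, 88 for G34R against G34V, 535 for G34R against set2Δ and 404 for G34V against set2Δ, which follows from the larger change required. With protein-coding genes alone, those changed at least 2-fold numbered 28, 37, 162, 41, 163 and 130 in the same order (58, 70, 452, 81, 360 and 284 over all classes), as noncoding genes were left out. With at least 1 CPM in 6 libraries, 32 were left for G34R against WT, 47 for G34R against G34V and 238 for G34R against set2Δ. Lists called numbered 14, 13, 11, 8, 9 and 8 with camera's preset correlation, 2, 2, 1, 2, 1 and 2 with an estimated correlation, and 23, 20, 25, 18, 26 and 24 with fry. For G34R against set2Δ, fry's rotation test called the heterochromatin machinery (24 genes, adjusted p = 0.0229) and DNA replication (34 genes, adjusted p = 0.000820) in the direction opposite to camera, which called neither of them. Shared calls of genes changed at least 2-fold numbered 15 for G34R and set2Δ, 43 for G34V and set2Δ and 12 for G34R and G34V. With 1 library left out, genes changed ranged from 2977 to 3311 for G34R against WT, 2840 to 3082 for G34V against WT and 4374 to 4526 for set2Δ against WT, and no call changed sign. With the counts of set2Δ replicate 3 halved, genes changed numbered 4610 for set2Δ against WT in place of 4627, and lists and overlaps were not run again. Without set2 the Set2 pathway list, an alternative chosen after the values were seen, lost its calls in set2Δ against WT, G34R against set2Δ and G34V against set2Δ (adjusted p = 0.23, 0.29 and 0.18), which shows that they rested on the deleted gene.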

Other observations

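Beyond the lists, 20 of 80 tested tRNA genes rose in G34R, 1 fell and 59 were not called, without a test of the class, and tRNA genes took 0.0027% of gene counts in G34R and 0.0020% in WT. Of 30 tested pseudogenes 18 rose and 8 fell in set2Δ, 11 and 10 in G34V and 10 and 6 in G34R, also without a test of the class. The mating-type gene mat1-Mi was at 0.560 CPM in WT and between 0.465 and 0.872 CPM in the mutants, and mat2-Pc and mat2-Pi had 0 counts in all 12 libraries. Reads that aligned to several places were left out of the counts, and shared sequence was not measured for these genes. The 0 counts therefore do not show whether mat2-Pc and mat2-Pi were absent or not expressed.

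Antisense RNAs in set2Δ: the bound on strand error below was chosen after the result was seen, and the other tests before. The 617 antisense RNAs named after their sense gene had a median log2 fold change of 0.54 in set2Δ. The lowest median over the scalings was also 0.54, so the choice among them does not explain the rise. These scalings put the median of all genes in set2Δ against WT between −0.0057 and 0.037. A larger error shared by all of them was not tested. The planned test of sense reads counted on the opposite strand met its mark for that explanation, at 139% of the increase, but cannot decide, since the ratio it used (25th percentile, 0.0654 in set2Δ and 0.0436 in WT) counts real antisense RNA as error and sets a level against an increase. A single rate of strand error bounded by the 10 most abundant sense genes would give 6.52% of the increase (bootstrap upper value 16.2%), which argues against 1 rate for all genes. Genomic DNA stays open. Its planned test was met, as the 5th percentile of coding RPKM was 9.83 times the density that the extra reads outside genes would give. Any small amount of DNA would meet that test. Taken as even over both strands of the whole genome, the density could account for 23.3% of the increase. Reads outside genes can come only from the part without annotation, so this density and share are understated, by an amount not computed. With genomic DNA and strand error that differs between genes open, the pattern is not called biological here.

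Subtelomeric genes in set2Δ: both tests were chosen before the result was seen. A strain difference at 1 chromosome end is argued against by medians of at least 0.3 at 4 of 4 ends. Reads shared between similar genes are argued against by a median of 1.78 in genes without a similar stretch in another gene. An effect of the loss of Set2, a difference between strains that affects all ends, and 1 culture for all 3 libraries could not be told apart and stay open.

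Tf2-13 in G34V: the test of the neighbours was chosen before the result was seen, and the other tests after it. Higher expression of all Tf2 elements is argued against by a median of −0.068 in the other 11. A wider rise of the region is argued against by a median of −0.15 in the 3 genes on each side. These neighbours lay between −0.25 and −0.04, and some were called lower, such as taf13 (−0.19, SE 0.030). A small decrease of the region is therefore not argued against, and its cause was not tested. A strain difference in this copy or its sequence could give the same log2 fold change of 5.46 and cannot be told apart from an effect of G34V.

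In set2Δ the changes of antisense RNAs and of their sense genes were correlated at 0.191 (Pearson, 550 pairs, adjusted p = 1.3e-05 by permutation with Benjamini-Hochberg), while the rank correlation was 0.047 (Spearman, p = 0.271 by permutation). Neither value was negative, and the Pearson value met the mark set in advance against a general fall of sense genes where antisense RNAs rose. Strand error and genomic DNA could raise this correlation and hide a negative link, so the test cannot decide. No positive link is claimed either. Gene length and change were weakly and negatively correlated, at −0.119 (Spearman, 5057 coding genes, adjusted p = 1.3e-05 by permutation with Benjamini-Hochberg), with a size between the marks set in advance for and against a link, and its cause was not tested. For each of the 6 comparisons, 1 of 10 splits of the 6 libraries called as many genes as the real one, the real one itself (3524, 3306, 4627, 3337, 4580 and 4123 genes for G34R, G34V and set2Δ against WT, G34R against G34V, and G34R and G34V against set2Δ). The highest other split called 0 genes with edgeR, with 338, 365, 374, 444, 353 and 438 at an unadjusted p under 0.05. Every other split puts libraries of both groups on each side, so real differences enter the spread and few calls are fixed in advance. Also, 10 splits are too few for a share under 0.05.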
